A study of Brassica rapa with 9 samples.

How the data were processed

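Total RNA from rosette leaves of Chinese cabbage (Brassica rapa) at the rosette stage was sequenced on an Illumina platform after Trizol extraction, per the labels' protocols. The 9 libraries fell into 3 groups of 3: the wild type 'FT', the mutant nhm3-1, and nhm3-1 with GA3. GA3 is gibberellic acid, and its dose and timing are not given in the sources used here. Group and replicate number were taken from the sample labels. The labels do not say that replicates came from separate plants, so all p-values measure only the spread between these samples, which may be technical.

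The authors deposited 1 table per library, with an estimated count per gene and an FPKM value per gene (fragments per kilobase, scaled to the size of the library), per the file headers. HISAT2 and DESeq2 are named without versions in the submitters' processing notes, and the genome build is not given in the sources used here. Of the estimated counts, 95.2% to 96.2% per library were whole numbers. The smallest FPKM in every table was 1, so a gene is listed for a library only at 1 FPKM or more. In total, 21557 genes were listed in at least 1 library, 14303 in all 9 and 19170 in 3 or more. Of all gene and library pairs, 34115 (17.6%) were unlisted. In 20 genes a single library had no value although all the others were above 3 FPKM, so some unlisted values may not be low ones. The tables also held 1050 genes assembled by the authors (identifiers starting with MSTRG). Gene names, descriptions, and KEGG and GO terms were taken from the tables themselves, and no genome was used here, so no coordinates are given.

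Estimated counts were rounded to whole numbers. An unlisted value was entered as the count equal to 1 FPKM in that library, obtained from the ratio of count to FPKM, which is the product of a library constant and a gene constant. This entry was not part of the design fixed before the data were examined; it was chosen once the limit was seen, and entering 0 instead was tried as an alternative. Means and SDs of FPKM also use 1 for unlisted values. Where a whole group was unlisted, the fold is a lower bound. Genes listed in at least 3 libraries that passed edgeR's filterByExpr were tested, 17725 in all, of which 847 were assembled genes.

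The summed estimated counts were 4670985, 4473638 and 4861535 for FT replicates 1 to 3, 5919061, 6233646 and 6045637 for nhm3-1, and 7622455, 6099634 and 6644262 for nhm3-1+GA3. Between 17215 and 18208 genes were listed per library. Replicates differed by more than sampling noise in all 9 within-group pairs (chi-square per degree of freedom of 4.25 to 26.5), so no library was treated as deposited more than once.

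Group differences were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; TMM factors, 1 model over all 9 libraries, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Errors of log2 fold changes are standard errors from that test. Genes that passed in nhm3-1 against FT and passed in the opposite direction in nhm3-1+GA3 against nhm3-1 were counted as moved back. Because both comparisons share the nhm3-1 libraries, this count was set beside 20 simulated draws with 3 unchanged groups.

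Before the data were examined, 30 gene lists were fixed: hormone synthesis and response, cell expansion and division, leaf form, photosynthesis, secondary metabolism, cell wall, ribosomes, stress, and markers of other tissues. Each list of at least 5 tested members was tested with camera (limma 3.58.1; log2 CPM, preset inter-gene correlation 0.01), adjusted over the 81 list and comparison pairs. Lists were matched by symbol and description, and 164 of 1515 matches named another protein. Those were picked from names alone before any test; member counts leave them out, camera used the lists as written, and camera without them was added as an alternative after the data were seen. KEGG and GO terms with 10 to 500 tested genes (704 terms) were tested in the same way, adjusted within each comparison.

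The rule for named genes, fixed before the data were examined, took any tested ent-kaurenoic acid oxidase gene, up to 4 members of each list with the smallest adjusted p, and the 6 largest rises and 6 largest falls. The last 12 had to be past the threshold, at 5 FPKM or more in the higher group, without overlap between the groups' libraries, and with a named annotation. The rule gives more genes than are named here; mostly those past the threshold are given. Many B. rapa genes have close copies that carry the same symbol, and how the authors' counting shared reads among them is not given in the sources used here, so values of single copies of multigene families are uncertain.

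Alternatives fixed before the data were examined were DESeq2's size factors and upper-quartile factors in edgeR, the Wald test of DESeq2 1.42.0, limma with trend on log2(FPKM + 1) or log2(FPKM + 0.1), no filter or a filter of 10 CPM in 3 libraries, 2-group fits, the replicate number as a block, a log2 fold change of at least 1, and each library left out in turn. For lists they were an estimated correlation and fry. Alternatives added after the data were seen were 0 for unlisted values, only genes listed in all 9 libraries, 2 libraries left out together, and removal of the trend with gene length by a lowess curve per library (span 0.3). Gene length was taken as the gene constant of the count to FPKM ratio, available for every tested gene.

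Simulated counts were used to test edgeR, DESeq2, limma on log2(FPKM + 1), the moved-back count and camera at its preset correlation. The counts were drawn from the real means, library sizes and dispersions, with 17725 genes of which 200 were changed. The other alternatives and the tests of explanations were not simulated in this way. The changed genes were drawn from those with a mean of 5 FPKM or more, so recovery at lower levels was not measured. In nhm3-1 against FT, edgeR recovered 48 of 100 genes at a log2 change of 1 and 97 of 100 at 2, and 5.2% of its calls were unchanged genes. In nhm3-1+GA3 against nhm3-1 it recovered 44 and 97, and 6% of its calls were unchanged genes. Of DESeq2's calls 11.3% and 15.8% were unchanged genes in those comparisons. At a log2 change of 1, limma recovered 36 and 34 of 100 genes there. In simulated nhm3-1+GA3 against FT with no change edgeR called 1 gene. Of 200 genes simulated to move back 129 were counted, and camera made 2 of 2 expected list calls and 0 others. The simulated genes varied independently of each other, so these runs do not measure errors of camera or edgeR where genes vary together. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.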

Results

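Gene expression was measured by RNA sequencing in rosette leaves of Chinese cabbage, a B. rapa crop whose inner leaves fold into a leafy head. The wild type 'FT', the mutant nhm3-1 and nhm3-1 with GA3 were each represented by 3 libraries of 4473638 to 7622455 estimated counts. The series title attributes the mutant's altered head to BrKAO2, which encodes ent-kaurenoic acid oxidase, an enzyme early in gibberellin biosynthesis. The comparisons therefore ask what the mutant changes in the leaf and which of those genes move the other way with GA3. No group of FT with GA3 was among the libraries. A reversal of the mutant's changes therefore cannot be told apart from a general response to the GA3 treatment.

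On the first principal component (50% of the variance) FT lay at -16.9, -32.9 and -33, and nhm3-1+GA3 replicates 1 and 2 at -36 and -40.6. The nhm3-1 replicates 1 and 3 lay at 57.8 and 70.9. In between lay nhm3-1 replicate 2 at 11.5 and nhm3-1+GA3 replicate 3 at 19.3. FT replicate 1 stood apart on the second component (12.9%) at 46.6.

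**Figure D1:**
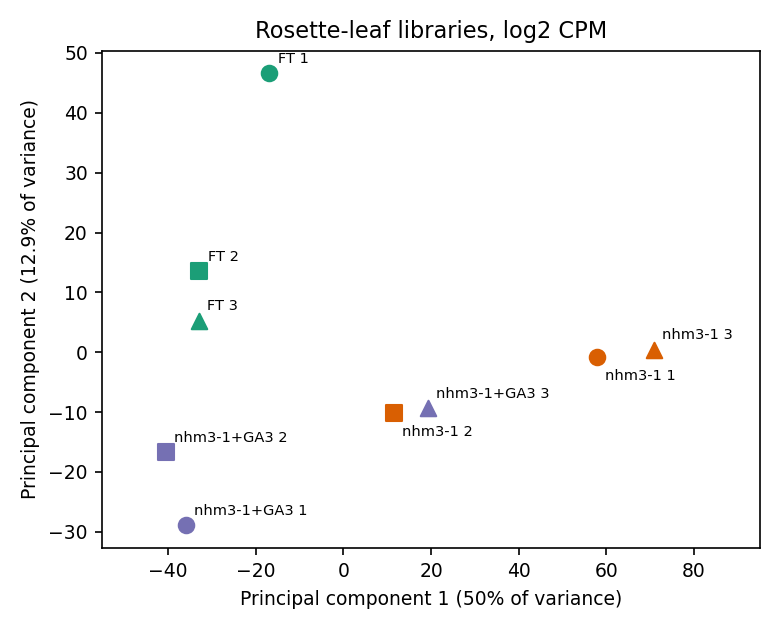
Principal components 1 and 2 of log2 CPM over the tested genes, 1 point per library, with colour for the group and marker shape for the replicate number. On component 1, nhm3-1 replicates 1 and 3 sit at 57.8 and 70.9, while nhm3-1 replicate 2 and nhm3-1+GA3 replicate 3 sit at 11.5 and 19.3.

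The KAO2 gene that the tables name (BraA01g029010.3C) was listed at 1.79 FPKM in FT replicate 1 and 1.04 FPKM in nhm3-1 replicate 3, and was unlisted in the other 7 libraries. It was too low to be tested, and a mutated gene can still be transcribed, so its level checks no label.

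In nhm3-1, 3 genes of gibberellin 20-oxidases, which act late in gibberellin synthesis, rose against FT. GA20OX3 (BraA03g002880.3C) stood at 1.15 ± 0.115 FPKM in FT and 6.04 ± 2.56 in nhm3-1 (SD, n = 3 each; log2 fold change 2.42 ± 0.39, edgeR adjusted p = 0.018). GA20OX2 (BraA10g010400.3C) rose from 1.22 to 2.97 FPKM and GA20OX1 (BraA01g016120.3C) from 1.19 to 2.53 FPKM. Both were near the listing limit in FT: GA20OX2 was unlisted in FT replicates 2 and 3 and GA20OX1 in FT replicate 3. Those values entered as 1 FPKM. The gibberellin 3-oxidase GA3OX1 (BraA06g011600.3C) stood at 3.96 ± 0.384 and 7.30 ± 2.04 FPKM and did not pass (edgeR adjusted p = 0.057, and 0.047 with the length trend removed). Of the 8 tested members of this list 3 rose and 0 fell (4 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.65. The list as written did not pass (camera adjusted p = 0.12); without matches to other proteins it gave 0.0038, and adjusted p = 0.50 with an estimated correlation.

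The gibberellin receptor genes GID1A and GID1B also rose. GID1A (BraA05g040050.3C) went from 14.01 ± 4.35 to 25.1 ± 2.66 FPKM, and GID1B (BraA09g052310.3C), unlisted in FT, reached 3.36 ± 0.492 FPKM, at least 3.36-fold higher. SCL3 (BraA06g003280.3C), a GRAS protein of the gibberellin pathway, rose from 2.597 to 5.78 FPKM. The DELLA repressor gene RGL2 (BraA05g041910.3C) fell from 28.03 ± 2.16 to 10.9 ± 3.13 FPKM (log2 fold change -1.33 ± 0.21, edgeR adjusted p = 0.018). Of 13 members of the perception list 5 rose and 1 fell (5 and 2 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.84). Of the 6 GASA genes, which gibberellin regulates, 0 passed (0 higher and 2 lower adjusted over the list alone), with a median log2 fold change of -0.97 and a camera adjusted p of 0.073; without FT replicate 3 that p was 0.030. The only tested gibberellin 2-oxidase had a log2 fold change of 0.21.

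**Figure D2:**
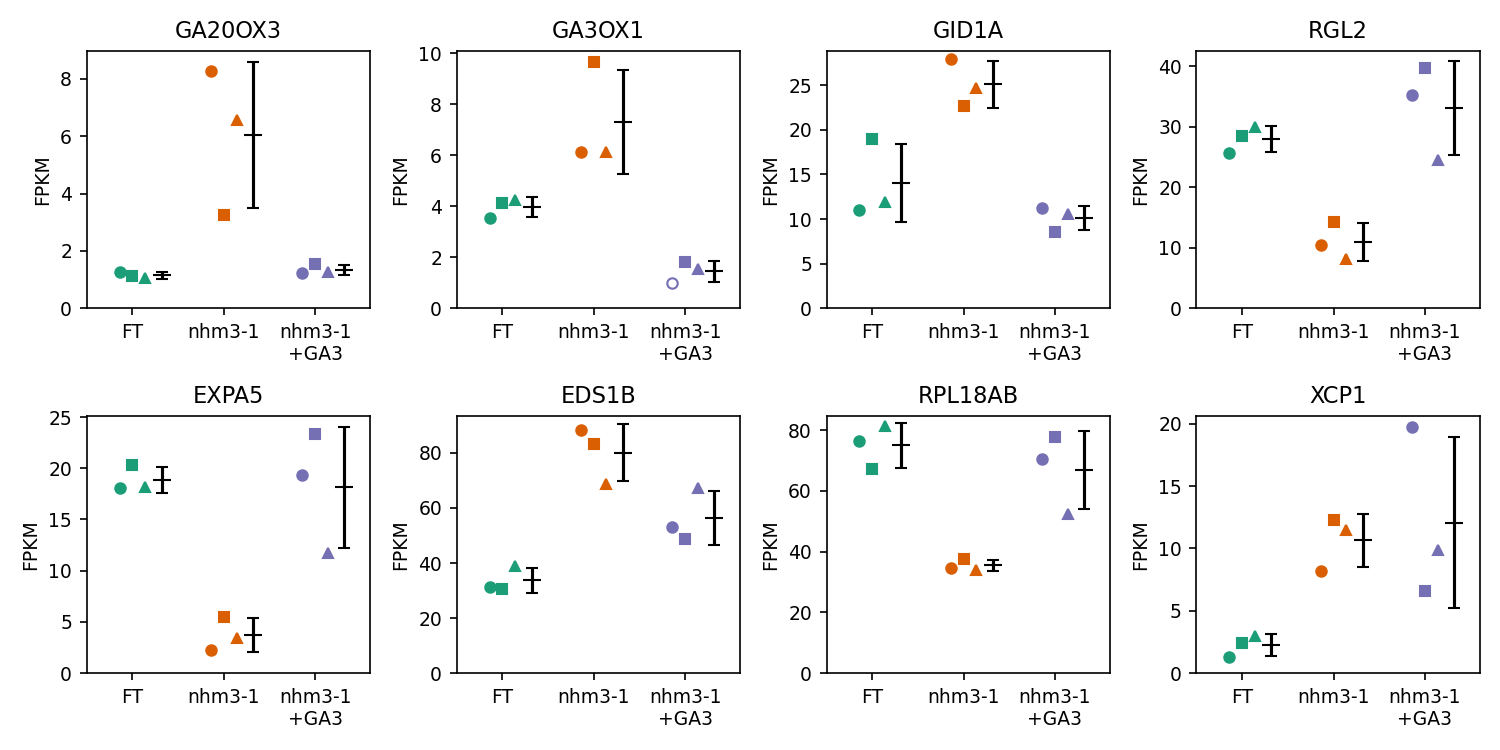
FPKM of 8 genes in each library (markers by replicate number; an open marker is a library in which the gene was unlisted and is drawn at 1 FPKM), with the group mean and SD in black, n = 3 per group. GA20OX3 averages 1.15, 6.04 and 1.34 FPKM and EXPA5 18.9, 3.73 and 18.2 FPKM in FT, nhm3-1 and nhm3-1+GA3, whereas XCP1 averages 2.25, 10.7 and 12.1 FPKM.

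Some expansin and ribosomal protein genes fell in nhm3-1. The expansin EXPA5 (BraA09g003690.3C), a wall-loosening protein, fell from 18.9 ± 1.24 to 3.73 ± 1.67 FPKM (log2 fold change -2.30 ± 0.30, edgeR adjusted p = 0.017), and EXPA3 (BraA05g007910.3C) and EXPA13 (BraA05g041750.3C) fell 2.36-fold and 1.91-fold. Of 28 expansins 3 fell (1 higher and 4 lower adjusted over the list alone), and the list was lower (camera adjusted p = 0.011; adjusted p = 0.66 with an estimated correlation). Cytosolic ribosomal protein genes fell in 107 of 330 cases and rose in 0 (251 lower adjusted over the list alone). Their median log2 fold change was -0.91, and camera's adjusted p was 4.16e-30, with adjusted p = 0.66 with an estimated correlation. RPL18AB (BraA03g036540.3C) fell from 74.99 ± 7.33 to 35.5 ± 1.94 FPKM, RPL18B (BraA06g033780.3C) from 30.9 to 10.8 FPKM and RPL32A (BraA01g009630.3C) from 125.4 to 41.5 FPKM. The ribosomal list's median deviation was -0.63, -0.07 and -1.05 in nhm3-1 replicates 1 to 3, and 0.29, 0.34 and 0.43 in FT. None of 31 cell division genes passed in edgeR (0 adjusted over the list alone), yet their list was lower, with a median log2 fold change of -0.56 (camera adjusted p = 0.0019; adjusted p = 0.66 with an estimated correlation). Its median deviation was -0.39, 0.09 and -0.65 in nhm3-1 and -0.26, 0.38 and 0.36 in FT. Of 26 xyloglucan endotransglucosylase genes 0 passed in edgeR (0 adjusted over the list alone; camera adjusted p = 0.27).

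**Figure D3:**
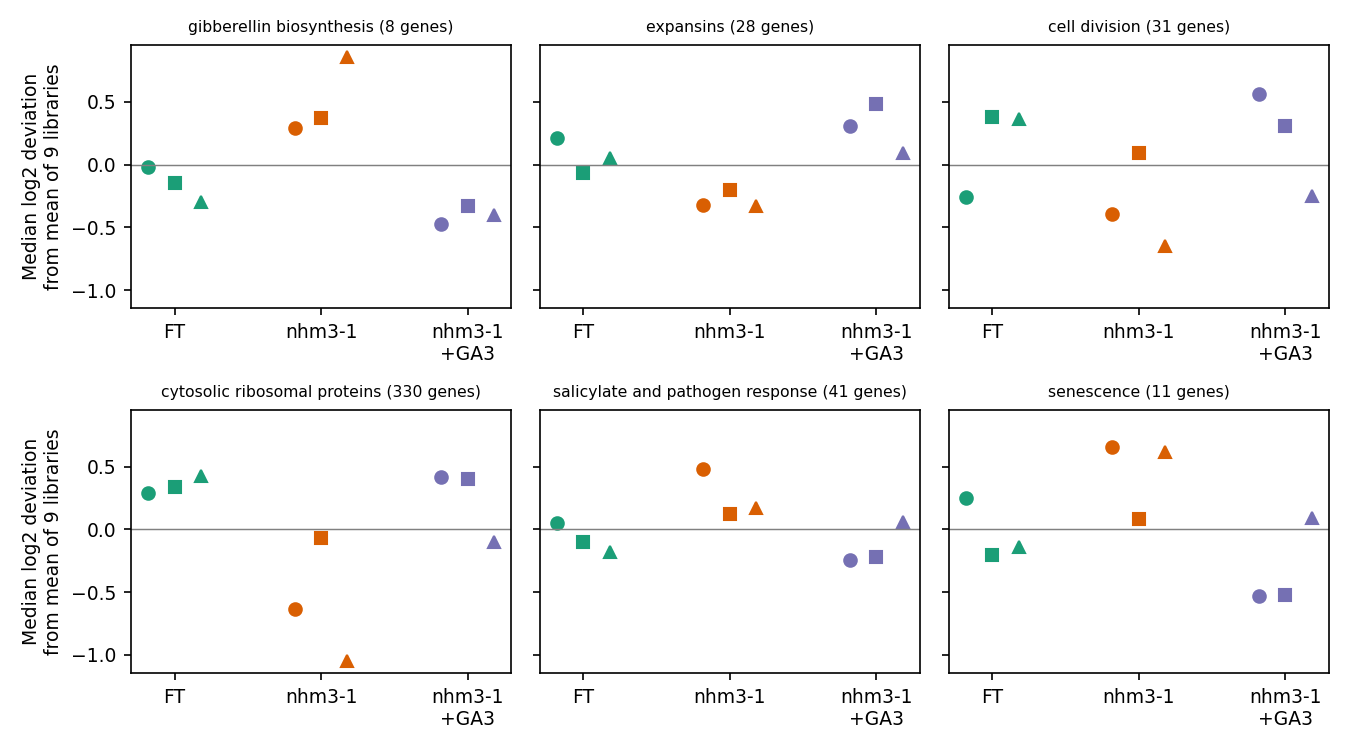
Median log2 CPM deviation of each list's members from their mean over the 9 libraries, 1 point per library (marker by replicate number), for 6 lists. The ribosomal protein median lies at -0.63, -0.07 and -1.05 in nhm3-1 against 0.29, 0.34 and 0.43 in FT, and the gibberellin biosynthesis median at 0.29, 0.37 and 0.86 in nhm3-1 against -0.47, -0.33 and -0.40 in nhm3-1+GA3.

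Several salicylate and pathogen genes rose in nhm3-1. EDS1B (BraA01g024750.3C), a regulator of immunity, rose from 33.7 ± 4.63 to 80.2 ± 10.3 FPKM (log2 fold change 1.29 ± 0.18, edgeR adjusted p = 0.017). The glucanase BG2 (BraA09g047910.3C) rose 3.45-fold, WRKY53 (BraA03g051480.3C) 2.83-fold and a pathogenesis-related protein 5-like gene (At1g75040, BraA06g014920.3C) 3.76-fold. Of 41 salicylate and pathogen genes 9 rose and 0 fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.021; adjusted p = 0.66 with an estimated correlation). Without nhm3-1 replicate 1 camera's adjusted p was 0.070 and the fold of At1g75040 2.44. The list's median deviation was 0.48, 0.12 and 0.17 in nhm3-1 replicates 1 to 3 and 0.05, -0.10 and -0.18 in FT. In the senescence list DIN1 (BraA01g002770.3C) rose 5.50-fold (3.33-fold without nhm3-1 replicate 3) and the chlorophyll breakdown gene SGR1 (BraA01g013510.3C) fell 1.92-fold, among 11 members (3 and 1 adjusted over the list alone). The senescence list as written was higher (camera adjusted p = 0.021; adjusted p = 0.66 with an estimated correlation), but not without matches to other proteins (0.18) nor without nhm3-1 replicate 1 (0.057). Its median deviation was 0.66, 0.08 and 0.62 in nhm3-1 and 0.25, -0.20 and -0.14 in FT. The jasmonate genes LOX4 (BraA02g021090.3C) and CYP74A (BraA02g030050.3C) rose 3.58-fold and 5.28-fold, 2 of 24 members (2 adjusted over the list alone; camera adjusted p = 0.88).

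Among other hormone lists, 1 auxin gene rose and 3 fell of 61 (1 and 3 adjusted over the list alone; camera adjusted p = 0.20, but 0.034 without FT replicate 3 and 0.044 without nhm3-1 replicate 3). IAA7 (BraA05g024080.3C) fell from 3.37 to 1.08 FPKM and SAUR32 (BraA03g024950.3C) 2.89-fold, and SAUR36 (BraA04g001580.3C) rose 4.14-fold. CYP734A1 (BraA07g017820.3C), which inactivates brassinosteroids, rose 3.43-fold, 1 of 10 brassinosteroid genes (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.88). The cytokinin dehydrogenase CKX6 (BraA09g052550.3C) rose 2.55-fold, 1 of 12 cytokinin genes (2 adjusted over the list alone; camera adjusted p = 0.43). Of 27 abscisic acid genes RD22 (BraA02g041540.3C) fell 2.98-fold and CYP707A3 (BraA02g031780.3C), unlisted in FT, was at least 3.84-fold higher, or 2.43-fold without nhm3-1 replicate 1 (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.85). Of 87 ethylene genes 6 rose, CTR1 (BraA10g032490.3C) among them at 2.29-fold, and 3 fell, ERF106 (BraA02g002410.3C) among them at 3.24-fold (7 and 4 adjusted over the list alone). The ethylene list did not pass (camera adjusted p = 0.094), but the value was 0.0057 without FT replicate 1 and 0.014 with the length trend removed. In the perception, cytokinin and glucosinolate lists the medians (-0.01, -0.16 and -0.04) were below 0 while camera's direction was up, and in the abscisic acid list the median was 0.01 and the direction down.

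Among leaf-form genes TCP11 (BraA09g040170.3C) rose 2.81-fold, while AS1 (BraA05g007920.3C), a determinant of leaf polarity, fell from 84.2 ± 12.1 to 43.5 ± 11.9 FPKM. Copies of TCP21 (BraA03g003460.3C, BraA02g002690.3C) fell 1.76-fold and 2.01-fold, making 1 rise and 3 falls among 50 members (2 and 5 adjusted over the list alone; camera adjusted p = 0.30). Of 89 light-harvesting and photosystem genes 8 fell and 1 rose (9 and 1 adjusted over the list alone), LHCB5 (BraA03g027230.3C) from 58.3 ± 6.42 to 29.9 ± 2.03 FPKM and CAB36 (BraA09g003290.3C) 1.73-fold. That list had a camera adjusted p of 0.21, and of 0.022 without nhm3-1 replicate 3. Glucosinolate genes moved both ways, 9 up and 2 down of 36 (10 and 8 adjusted over the list alone; camera adjusted p = 0.88). CYP83B1 (BraA08g007500.3C), UGT74C1 (BraA04g022880.3C) and SOT16 (BraA02g022100.3C) rose 3.55-fold, 1.97-fold and 2.44-fold, and a gene named MYB39 and described as MYB34-like (BraA01g044600.3C) fell 2.57-fold. Of 71 cell wall genes 4 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.63). COMT1 (BraA06g016590.3C) of lignin synthesis rose 2.91-fold and 4CLL7 (BraA09g024990.3C) 2.02-fold, and the cellulose synthase CESA5 (BraA03g004030.3C) fell 2.38-fold. In the flavonoid list of 18 genes ANT17 (BraA01g020510.3C) rose 2.12-fold and MYB12 (BraA06g034790.3C) fell 2.19-fold (1 and 2 adjusted over the list alone; camera adjusted p = 0.95). The heat stress factor HSFA4A (BraA01g010370.3C) rose 2.79-fold, 1 of 52 heat shock genes (0 adjusted over the list alone; camera adjusted p = 0.43), and 0 of 23 flowering time genes passed in edgeR (0 adjusted over the list alone; camera adjusted p = 0.44).

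Markers of other tissues gave mixed results. The xylem proteases XCP1 (BraA01g003050.3C) and XCP2 (BraA07g015520.3C, BraA08g027620.3C) rose 4.74-fold, 6.86-fold and 2.59-fold, 3 of 16 vascular genes (3 adjusted over the list alone). The vascular list as written did not pass (camera adjusted p = 0.17), and without matches to other proteins it gave 0.015, with adjusted p = 0.58 with an estimated correlation. The guard cell list was lower, with a median log2 fold change of -0.49 (camera adjusted p = 0.022; adjusted p = 0.66 with an estimated correlation), although 0 of its 15 members passed in edgeR (0 adjusted over the list alone). Without nhm3-1 replicate 1 its adjusted p was 0.090. Its median deviation was -0.61, -0.09 and -0.50 in nhm3-1 and 0.03, 0.37 and 0.25 in FT. Of 5 trichome genes 0 passed in edgeR (0 adjusted over the list alone; camera adjusted p = 0.43). Of 2 shoot meristem and 3 floral genes 0 passed (0 adjusted over each list alone); most matches of these lists as written named other proteins, so camera's test of them does not measure these genes, and the 1 root gene had a log2 fold change of -0.17.

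Among the genes chosen by size of change in nhm3-1, NAS3 (BraA06g006140.3C), a nicotianamine synthase, rose from 3.11 ± 2.19 to 71.0 ± 40.2 FPKM and CYP76AH1 (BraA03g050380.3C) from 3.32 ± 2.36 to 45.5 ± 23.5 FPKM. An endochitinase (BraA03g022850.3C) rose 12.7-fold and MLP31 (BraA07g014290.3C) 8.40-fold. A GDSL esterase (At2g03980, BraA06g038960.3C) and the metacaspase AMC9 (BraA02g001310.3C), unlisted in FT, were at least 8.71-fold and 8.24-fold higher. The alkane hydroxylase CYP96A15 (BraA09g018290.3C), an enzyme of wax synthesis, stood at 24.7 ± 6.96 FPKM in FT and was unlisted in nhm3-1, at least 24.7-fold lower, and MYB306 (BraA02g022420.3C) was at least 8.12-fold lower. MSTRG.14702, a glutathione S-transferase T3-like gene, fell 19.0-fold, MLP423 (BraA07g013840.3C) 9.69-fold and AEE4 (BraA07g040690.3C) 9.19-fold. MLP423 and AEE4 stood at 10.53 and 11.79 FPKM in nhm3-1 replicate 2, at 1.39 and 2.05 in replicate 1 and unlisted in replicate 3, and without replicate 2 their folds were 34.9 and 29.8. Without FT replicate 1 the folds of NAS3 and CYP76AH1 were 36.7 and 22.99 in place of 22.8 and 13.7, without FT replicate 2 that of MLP31 was 13.2, and without nhm3-1 replicate 3 the bound for At2g03980 was 5.45. The zinc finger BED gene Os03g0733400 (BraA09g040710.3C) stood at 11.1 ± 0.904 FPKM in FT and was unlisted in all 6 other libraries, at least 11.1-fold lower. In all, 1478 of 17725 genes passed in nhm3-1 against FT, 869 higher and 609 lower; upper-quartile factors gave 662 higher and 725 lower, and removal of the length trend 759 and 406. Of the 1773 shortest genes 43 were higher and 149 lower (median log2 fold change -0.24), and the 1773 longest had a median of 0.16.

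The count moved strongly with single libraries left out, in fits that have fewer samples. Without FT replicate 1, 2 or 3 it was 2, 4 and 2, and without nhm3-1 replicate 1 or 3 it was 2 and 4. Without nhm3-1 replicate 2 it was 3370, and without nhm3-1+GA3 replicate 1 or 3 it was 805 and 2361. At an edgeR adjusted p under 0.1, 1536, 1118 and 1110 genes passed without FT replicates 1 to 3, against 3263 with all libraries. Without nhm3-1 replicates 1 and 3 that looser threshold gave 467 and 636 genes. DESeq2 called 2276 genes, edgeR with 0 for unlisted values 334, without a filter 286, and with a log2 fold change of at least 1 918. Without both intermediate libraries (nhm3-1 replicate 2 and nhm3-1+GA3 replicate 3) edgeR called 4577. Over the 14234 tested genes listed in all 9 libraries, where no value had to be entered, it called 1488.

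With GA3, 4 gibberellin biosynthesis genes fell. GA3OX1 fell from 7.30 ± 2.04 to 1.45 ± 0.409 FPKM (log2 fold change -2.32 ± 0.29, edgeR adjusted p = 0.0074) and GA20OX3 from 6.04 ± 2.56 to 1.34 ± 0.166 FPKM (-2.15 ± 0.36, edgeR adjusted p = 0.019; SD, n = 3). GA20OX2 and GA20OX1, unlisted with GA3, were at least 2.97-fold and 2.53-fold lower. Thus 4 of 8 biosynthesis genes fell and 0 rose (4 adjusted over the list alone), with a median log2 fold change of -1.01. The list as written did not pass (camera adjusted p = 0.23); without matches to other proteins it gave 2.0e-04, with adjusted p = 0.45 with an estimated correlation. The receptors GID1A and GID1B fell 2.47-fold and 2.87-fold and SCL3 4.33-fold, while RGL2 rose from 10.9 ± 3.13 to 33.1 ± 7.74 FPKM. With GA3, GID1B was unlisted in replicates 1 and 2, SCL3 in replicate 3 and GA3OX1 in replicate 1. Those values entered as 1 FPKM, so these 3 folds rest in part on the listing limit. In the perception list 2 of 13 rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.88). Of the 6 GASA genes 0 passed in edgeR (0 adjusted over the list alone; camera adjusted p = 0.30).

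Some expansin and ribosomal protein genes rose with GA3. EXPA5 went from 3.73 ± 1.67 to 18.2 ± 5.89 FPKM (log2 fold change 2.29 ± 0.30, edgeR adjusted p = 0.0077), and EXPB3 (BraA03g054290.3C) and EXPA3 rose 2.84-fold and 2.22-fold. These were 3 of 28 expansins (7 adjusted over the list alone; camera adjusted p = 0.00023; adjusted p = 0.66 with an estimated correlation). Of 330 ribosomal protein genes 35 rose and 0 fell (217 adjusted over the list alone), with a median log2 fold change of 0.81 (camera adjusted p = 1.24e-28; adjusted p = 0.66 with an estimated correlation). RPS12C (BraA03g017070.3C) rose 3.55-fold, RPL18AB 1.89-fold and RPL18B 2.41-fold. The list's median deviation was 0.42 and 0.40 in nhm3-1+GA3 replicates 1 and 2 and -0.10 in replicate 3. The cell division list was higher, with a median of 0.59 and 0 of 31 members past edgeR's threshold (0 adjusted over the list alone; camera adjusted p = 0.00045; adjusted p = 0.66 with an estimated correlation). In that list, deviations were 0.56, 0.31 and -0.25 in nhm3-1+GA3 replicates 1 to 3. TCP21 (BraA03g003460.3C) and TCP15 (BraA07g030260.3C) rose 2.26-fold and 2.74-fold, 2 of 50 leaf-form genes (4 higher and 1 lower adjusted over the list alone). The leaf-form list was higher (camera adjusted p = 0.022; adjusted p = 0.66 with an estimated correlation), but not without nhm3-1+GA3 replicate 2 (0.095) nor without matches to other proteins (0.11). Of 71 cell wall genes 4 rose and 1 fell (8 and 1 adjusted over the list alone). CESA5, PAL4 (BraA05g036420.3C) and PAL1 (BraA05g008320.3C), the last 2 of phenylpropanoid synthesis, rose 2.27-fold, 2.04-fold and 2.58-fold, and COMT1 (BraA06g016590.3C) fell 1.97-fold. That list was higher (camera adjusted p = 0.022; adjusted p = 0.66 with an estimated correlation), but its adjusted p was 0.099 without nhm3-1 replicate 1 and 0.12 without nhm3-1+GA3 replicate 1. In nhm3-1 replicate 2 and nhm3-1+GA3 replicate 3 the median deviation was 0.03 and -0.07 for leaf form and 0.03 and -0.03 for the cell wall.

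A few salicylate and pathogen, senescence and ethylene genes fell with GA3. BG2 fell 3.60-fold, the pathogenesis-related gene At1g75040 (BraA06g014920.3C) 5.33-fold and WRKY53 2.79-fold, 3 of 41 salicylate and pathogen genes (1 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.00060; adjusted p = 0.66 with an estimated correlation). PAO (BraA01g025910.3C) of chlorophyll breakdown fell from 71.0 ± 7.495 to 30.1 ± 5.57 FPKM (log2 fold change -1.22 ± 0.18, edgeR adjusted p = 0.013), 1 of 11 senescence genes (6 adjusted over the list alone; camera adjusted p = 0.00078; adjusted p = 0.66 with an estimated correlation). ERF2 (BraA02g033740.3C) and an ACC oxidase homolog (At3g61400, BraA09g051010.3C) fell 1.85-fold and 2.05-fold, 2 of 87 ethylene genes (2 higher and 3 lower adjusted over the list alone). The ethylene list was lower (camera adjusted p = 0.022; adjusted p = 0.66 with an estimated correlation), with 0.054 without nhm3-1 replicate 1 and 0.066 without nhm3-1+GA3 replicate 1. The median deviation of the senescence list was 0.66, 0.08 and 0.62 in nhm3-1 and -0.53, -0.52 and 0.09 in nhm3-1+GA3. In nhm3-1 replicate 2 and nhm3-1+GA3 replicate 3 it was 0.12 and 0.06 for salicylate and pathogen genes and 0.05 and 0.01 for ethylene. Without nhm3-1 replicate 1 the fold of At1g75040 was 3.45. Of 24 jasmonate genes MYC2 (BraA05g023030.3C), LOX4 and TIFY11A (BraA09g057760.3C) fell 1.73-fold, 3.14-fold and 2.61-fold (5 adjusted over the list alone; camera adjusted p = 0.20). Of 36 glucosinolate genes SUR1 (BraA09g012050.3C) and UGT74C1 fell 3.31-fold and 2.13-fold, and MYB39 (BraA01g044600.3C) and FMOGS-OX5 (BraA08g031160.3C) rose 2.33-fold and 3.31-fold, in all 2 rises and 4 falls (2 and 9 adjusted over the list alone; camera adjusted p = 0.55). CYP734A1, unlisted with GA3, was at least 3.62-fold lower, CYP90A1 (BraA10g028480.3C) of brassinosteroid synthesis fell 1.73-fold and CKX6 2.76-fold. IAA7, SAUR32 and RD22 rose 2.38-fold, 3.07-fold and 2.71-fold, the light-harvesting gene LHCB5 1.60-fold, and the chalcone synthase CHS3 (BraA02g005190.3C) 3.53-fold (5.46-fold without nhm3-1 replicate 2). Of the 27 lists tested 19 did not pass (camera adjusted p of 0.073 to 0.93). Among those 19, the guard cell and cytokinin lists were at 0.049 each without nhm3-1 replicate 2, guard cells at 0.0066 without nhm3-1+GA3 replicate 3 and at 0.0039 without both intermediate libraries, and light harvesting at 0.044 without nhm3-1 replicate 3 and 0.040 without nhm3-1+GA3 replicate 1. Without matches to other proteins the flavonoid list gave 0.0086 and the cytokinin list 0.047, each with adjusted p = 0.58 with an estimated correlation. In the brassinosteroid, abscisic acid and vascular lists the medians (0.06, 0.01 and 0.17) were above 0 while camera's direction was down.

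Among the genes chosen by size of change with GA3, CYP96A15 and the lipid-transfer protein WAX9A (BraA05g007090.3C), both unlisted in nhm3-1, reached 43.8 ± 42.8 and 20.9 ± 17.3 FPKM, at least 43.8-fold and 20.9-fold higher, and the polygalacturonase At1g48100 (BraA09g061760.3C) at least 7.61-fold. A further lipid-transfer protein (BraA02g039660.3C) rose from 13.5 ± 1.24 to 132 ± 63.7 FPKM, CHAT (BraA05g041930.3C), which makes a green leaf volatile ester, 11.8-fold, and the wax gene CER2 (BraA01g015290.3C) 8.17-fold. A copy of MLP31 (BraA07g035570.3C) fell from 75.4 ± 25.2 to 4.02 ± 2.99 FPKM (log2 fold change -4.23 ± 0.46, edgeR adjusted p = 0.0044) and a neighbouring copy (BraA07g035580.3C) 9.21-fold. PSOMT1 (BraA03g059240.3C), SBP3 (BraA07g009310.3C), the terpene synthase TPS10 (BraA03g025720.3C) and BOI (BraA01g011030.3C) fell 11.8-fold, 9.58-fold, 8.77-fold and 8.46-fold. In nhm3-1+GA3 replicate 3 CYP96A15 and WAX9A stood at 1.4 and 2.29 FPKM, near the listing limit. Without replicate 2 of that group their bounds were 22.3-fold and 13.01-fold, and the folds of CER2 and of MLP31 (BraA07g035570.3C) were 4.52 and 32.7, the latter 18.7 with all libraries. Without nhm3-1+GA3 replicate 3 the fold of SBP3 was 16.9, and without nhm3-1 replicates 1 and 3 those of PSOMT1 and BOI were 7.02 and 5.53. In all 527 genes passed in nhm3-1+GA3 against nhm3-1, 285 higher and 242 lower; limma on log2(FPKM + 1) gave 71 higher and 150 lower.

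This count, too, moved strongly with single libraries left out, in fits that have fewer samples. It was 213, 155 and 149 without FT replicates 1 to 3 and 23, 2464 and 40 without nhm3-1 replicates 1 to 3. Without nhm3-1+GA3 replicates 1 to 3 it was 10, 24 and 2553. DESeq2 called 1424 genes, limma 221, a fit of the 2 groups alone 32, and edgeR without a filter 54 higher and 69 lower. With 0 for unlisted values edgeR called 144, over genes listed in all 9 libraries 487, and without both intermediate libraries 4672.

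Of the 1478 genes changed in nhm3-1, 375 passed with GA3 in the opposite direction and 0 in the same direction in edgeR. Among them were GA20OX3, GID1A, RGL2, EXPA5, BG2, WRKY53, CESA5 and CYP96A15. Of the 375, 177 were higher in nhm3-1 and lower with GA3, where independent lists would share 11.9, and 198 lower and then higher, where they would share 9.79. In 20 simulated draws without any effect the highest count was 0, but at most 1 gene was called in nhm3-1 against FT there, so that 0 does not measure what the shared nhm3-1 libraries add. The log2 fold changes of the comparisons correlated across genes (which are not independent replicates) at r = -0.80, against -0.49 on average in the draws, and their covariance was -0.288 against -0.0461. The 3 shared nhm3-1 libraries cannot be divided so that each comparison keeps 2 of its own, so part of the excess may come from sharing them. Without FT leaves given GA3, genes that moved back also cannot be told apart from genes that respond to GA3 in any genotype. The count was 0, 1 and 0 without FT replicates 1 to 3, 0, 1948 and 2 without nhm3-1 replicates 1 to 3, and 9, 19 and 1509 without nhm3-1+GA3 replicates 1 to 3. DESeq2 gave 971, limma 159, fits of 2 groups 22, and edgeR without a filter 64. With 0 for unlisted values edgeR gave 83, over genes listed in all 9 libraries 346, and without both intermediate libraries 3395.

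Between nhm3-1+GA3 and FT few genes passed the test. LARP1A (BraA08g001090.3C), unlisted in FT, reached 6.73 ± 2.48 FPKM with GA3, at least 6.73-fold higher. The pinoresinol reductase PRR1 (BraA05g023720.3C) rose 5.68-fold and the pectinesterase PME25 (BraA01g040060.3C) from 10.1 ± 0.820 to 21.98 ± 1.36 FPKM (log2 fold change 1.19 ± 0.14, edgeR adjusted p = 0.016), having stood at 19.6 FPKM in nhm3-1. MSTRG.14702 fell 15.8-fold and Os03g0733400 was at least 11.1-fold lower, as in nhm3-1. The annotated fabG gene (BraA04g004790.3C) fell from 38.6 ± 2.16 to 7.54 ± 3.72 FPKM, BHLH28 (BraA09g022350.3C) 2.87-fold, and the cytochrome P450 genes CYP71B37 (BraA02g036850.3C) and CYP81D1 (BraA07g016610.3C) 2.75-fold and 2.18-fold. The xylem proteases XCP1 and XCP2 (BraA07g015520.3C), which rose in nhm3-1, stood at 12.1 ± 6.85 and 9.33 ± 4.56 FPKM with GA3, against 2.25 ± 0.857 and 1.26 ± 0.442 in FT (edgeR adjusted p = 0.088 and 0.063). GA3OX1 stood at 1.45 against 3.96 FPKM (edgeR adjusted p = 0.20). Without nhm3-1+GA3 replicate 2 the edgeR adjusted p was 0.020 for XCP1 and 0.0066 for XCP2, and without both intermediate libraries 0.047 for XCP2. DESeq2 called all 3 genes (adjusted p = 1.65e-05, 1.95e-06 and 0.048). In nhm3-1+GA3 replicates 1 to 3 XCP1 stood at 19.73, 6.57 and 9.87 FPKM and XCP2 at 13.19, 4.3 and 10.5. Leaving out replicate 2 thus removes the lowest library of both genes. In FT, XCP2 stood at 1.77 and 1.01 FPKM and was unlisted in replicate 3.

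No list member passed in this comparison in edgeR over all genes, where 1468 of 17725 genes had an unadjusted p under 0.05. The cell wall list was higher, with a median log2 fold change of 0.25 (0 of 71 members past the threshold, 11 higher adjusted over the list alone; camera adjusted p = 3.06e-05; adjusted p = 0.66 with an estimated correlation). The flavonoid list was higher (median 0.44 over 18 genes, 0 past the threshold and 0 adjusted over the list alone; camera adjusted p = 0.043; adjusted p = 0.66 with an estimated correlation). Its adjusted p was 0.24 without FT replicate 3, 0.058 without nhm3-1 replicate 1, 0.18 and 0.11 without nhm3-1+GA3 replicates 1 and 2, 0.068 without matches to other proteins and 0.091 with the length trend removed. The jasmonate list was lower (median -0.14 over 24 genes, 3 lower adjusted over the list alone; camera adjusted p = 0.022; adjusted p = 0.66 with an estimated correlation), with 0.15 and 0.11 without FT replicates 1 and 3 and 0.11 without nhm3-1+GA3 replicate 2. Ribosomal protein genes had a median of -0.10 (0 of 330 adjusted over the list alone; camera adjusted p = 0.020; adjusted p = 0.91 with an estimated correlation). Their adjusted p was 0.21 without FT replicate 3 and 0.15 with the length trend removed, and without nhm3-1+GA3 replicate 3 the direction turned to higher (0.67). The vascular list (16 genes, 6 higher adjusted over the list alone) had a camera adjusted p of 0.27 as written and of 0.0015 without matches to other proteins, with adjusted p = 0.50 with an estimated correlation. Among the 23 lists that did not pass (camera adjusted p of 0.20 to 0.95), leaving out nhm3-1+GA3 replicate 3 gave 8.1e-04 for light harvesting, 0.026 for leaf form, 0.035 for cell division and 0.041 for abscisic acid. Without both intermediate libraries these 4 lists also passed (0.0011, 0.024, 0.027 and 0.0498) and senescence gave 0.045, and with the length trend removed leaf form gave 0.044. For gibberellin biosynthesis, cell division, leaf form and trichomes the medians were -0.10, -0.08, -0.01 and -0.03 while camera's direction was up. For flowering time and heat shock they were 0.09 and 0.03 while its direction was down.

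In all 13 genes passed, 4 higher and 9 lower, and 6 and 8 with the length trend removed. DESeq2 called 110, 64 higher and 46 lower, and edgeR without a filter 8, with 0 for unlisted values 21, over genes listed in all 9 libraries 7, and without both intermediate libraries 43, 27 higher and 16 lower. The count was 2, 3 and 4 without FT replicates 1 to 3, 6 without nhm3-1 replicate 1, and 1 and 27 without nhm3-1+GA3 replicates 1 and 2, the 27 being 20 higher and 7 lower.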

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

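The entry of 0 for unlisted values, the restriction to genes listed in all 9 libraries, the joint omission of nhm3-1 replicate 2 and nhm3-1+GA3 replicate 3, the length trend, the removal of wrong list matches and the estimated correlation for annotation terms were tests chosen after the data were seen; the other alternatives were planned. For the counts of changed genes in nhm3-1 against FT, nhm3-1+GA3 against nhm3-1, nhm3-1+GA3 against FT and of genes that moved back (1478, 527, 13 and 375), the Wald test of DESeq2 gave 2276, 1424, 110 and 971. Without a filter edgeR gave 286, 1.2e+02 (54 higher and 69 lower), 8 and 64, with 0 for unlisted values 334, 144, 21 and 83, and without the 2 intermediate libraries 4577, 4672, 43 and 3395. In nhm3-1+GA3 against nhm3-1 and in genes that moved back, limma gave 221 and 159 on log2(FPKM + 1) and 230 and 167 on log2(FPKM + 0.1), and fits of only the 2 groups compared 32 and 22. A log2 fold change of at least 1 left 918 genes in nhm3-1 against FT. Genes listed in all 9 libraries gave 1488, 487, 7 and 346 for the 4 counts. For DESeq2's size factors, upper-quartile factors, 10 CPM and the removal of the length trend all 4 counts lay within 1.5 times the reported ones.

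With each library left out in turn the counts ran from 2 to 3370, from 10 to 2553, from 1 to 27 and from 0 to 1948. Over those 9 fits at least 3599, 2592 and 1040 genes had an unadjusted p under 0.05 in edgeR, and log2 fold changes correlated with the reported ones at 0.96, 0.96 and 0.88 or more. Many genes lay near the threshold: in nhm3-1 against FT 5148 genes had an unadjusted p under 0.05, 3263 an adjusted p under 0.1 and 1478 one under 0.05. Fits that leave out a library have fewer samples; for the other changes the cause was not tested.

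Of 18 list calls camera made 0 with an estimated correlation, fry made 1, and leaving out single libraries gave 12 to 22. Without wrong matches there were 21. Ribosomal proteins in nhm3-1+GA3 against FT turned from lower to higher without nhm3-1+GA3 replicate 3 (adjusted p = 0.67) and without the 2 intermediate libraries (0.57), with 4.38e-05 to 0.67 over the libraries left out. Of the 117, 112 and 49 annotation terms called 0 were called with an estimated correlation.

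The replicate numbers did not pair the libraries: 3 of 9 same-numbered pairs deviated together with a correlation over 0.1 (range -0.27 to 0.41), and 3 of 9 libraries matched best with their own number. With the replicate number as a block the counts were 2016, 1018, 14 and 770, and 18 lists were called, with no list call changed. Among 127 tested log2 fold changes of named genes 0 turned direction where either fit called them, under the alternatives that tested them (all 127, but 82 over genes listed in all 9 libraries and 91 at 10 CPM); all but 5 stayed on their side of the threshold under the block and under DESeq2, 120 under upper-quartile factors, 91 under limma on log2(FPKM + 1), 46 with 0 for unlisted values and 52 without a filter. With each library left out, 40, 36 and 36 did so for FT replicates 1 to 3, 19, all but 4 and 25 for nhm3-1, and 53, 73 and all but 3 for nhm3-1+GA3. Of the 19170 genes listed in 3 or more libraries 17725 passed the count filter, and below it or the listing limit of 1 FPKM no difference was detectable.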

Other observations

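All tests of explanations below were chosen after the patterns were seen, except the split counts and the search for copies of the same name that rose; the annotation term tests were planned, their estimated correlation was not. In the annotation terms, of 25 genes under nucleosome organization 10 fell and 0 rose in nhm3-1 against FT (median log2 fold change -0.93; camera adjusted p = 4.21e-08; adjusted p = 0.78 with an estimated correlation), and 10 rose with GA3 (median 0.95; camera adjusted p = 9.32e-08; adjusted p = 0.76 with an estimated correlation). Of 47 genes with UDP-glucosyltransferase activity 10 rose in nhm3-1 and 0 fell (median 0.48; camera adjusted p = 0.00021; adjusted p = 0.78 with an estimated correlation), and of 74 amino acid transport genes 14 rose and 0 fell (median 0.35; camera adjusted p = 0.00027; adjusted p = 0.78 with an estimated correlation). With GA3, 2 of 15 genes with water transmembrane transporter activity rose and 0 fell (median 0.67; camera adjusted p = 0.00018; adjusted p = 0.76 with an estimated correlation). Genes of polysaccharide lyase activity rose in 5 of 16 cases (median 0.66; camera adjusted p = 2.44e-06; adjusted p = 0.76 with an estimated correlation). In nhm3-1+GA3 against FT the term most clearly higher was L-phenylalanine metabolism (10 genes, 0 past edgeR's threshold, median 0.65; camera adjusted p = 0.00031; adjusted p = 0.95 with an estimated correlation). Of 704 terms, 61 were higher and 56 lower in nhm3-1 against FT, 77 and 35 in nhm3-1+GA3 against nhm3-1, and 45 and 4 in nhm3-1+GA3 against FT, and with an estimated correlation 0 were called in each comparison.

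The first pattern was the place of nhm3-1 replicate 2 and nhm3-1+GA3 replicate 3 between the groups. On 33 genes that set nhm3-1+GA3 apart from both other groups, chosen without these 2 libraries, nhm3-1 replicate 2 lay at a median of 0.05 (upper quartile 0.31) and nhm3-1+GA3 replicate 3 at 0.61 (lower quartile 0.40), where 0 is the mean of FT and nhm3-1 and 1 is nhm3-1+GA3. An exchange of their labels needs nhm3-1 replicate 2 at the GA3 level, and its position argues against that exchange. Their gibberellin biosynthesis medians (0.37 and -0.40) also lay with their labelled groups. On the other side, the grouping that an exchange gives called 1850 genes in nhm3-1+GA3 against nhm3-1, where the real labels called 527. Mixing with nhm3-1 RNA needs 1 share for all genes in nhm3-1+GA3 replicate 3. The median linear positions of 302 genes higher and 327 lower in nhm3-1 differed by 0.46 (0.67 and 0.21, quartiles 0.57 to 0.81 and 0.07 to 0.34). These genes were, however, chosen for a fold of at least 4 in the same libraries that set the ends of the scale. That choice can move the 2 medians apart in this direction and was not controlled, so mixing is not decided for this library. For nhm3-1 replicate 2 the difference was 0.21 (0.67 and 0.46) and the quartiles overlapped (0.52 to 0.80 and 0.26 to 0.69), so mixing with other leaves and a real difference between plants cannot be told apart there; differences of leaf age or GA3 response between plants were not tested.

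The second pattern was the lower level of cytosolic ribosomal protein genes in nhm3-1. These genes are short, and short genes were lower in general. After the trend with length in all other genes was subtracted, the median log2 fold change of the 330 genes was -0.79 (upper quartile -0.57), against -0.91 before, which argues against length as the whole cause. Set against other genes of like abundance the median was -0.94 (upper quartile -0.72), which argues against a shift shared by genes of that abundance. A scaling factor moves all genes alike, and the median over all genes was -0.00. The comparison is therefore no separate test of the scaling between libraries. What stays open includes a difference in growth, leaf age or harvest time, since the mutation is the group itself and the list also varied within nhm3-1. No biological explanation was tested, and no technical one beyond length and abundance.

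The third pattern was 2 genes at 5 FPKM or more listed in every FT library and in none of the other 6, Os03g0733400 and ORG2 (BraA04g003650.3C, 11.04 ± 14.4 FPKM, from 1.71 to 27.61), the latter named after its values were seen. Among the other choices of 3 libraries out of 84, the highest count was 1, and 2 genes were listed in all 6 other libraries and in no FT library. At the level of the lowest FT library at least 165 counts were expected for Os03g0733400 in each of the 6 libraries, which argues against too few reads. For ORG2 the expected count was 8, and its lowest FT library, at 1.71 FPKM, was near the listing limit. For that gene too few reads, a level that varies or is somewhat lower, and a lost or silent gene cannot be told apart. For Os03g0733400, 0 of 2 tested genes of its description rose in nhm3-1 in edgeR, and their summed level differed by -0.32 of the level it lost (standard error 0.19), which argues against reads counted for a tested copy of that name; ORG2 had no description to search with. A difference in genetic background between FT and the mutant line was not tested.

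For the counts of changed genes, 10 splits of 6 libraries are too few for a share under 0.05. In nhm3-1 against FT 1 of the 10, the real one with 1478 genes, called as many, and the highest other count was 0. In nhm3-1+GA3 against FT 1 of the 10 did, with 13 genes and a highest other count of 0. In nhm3-1+GA3 against nhm3-1 the real split gave 527 genes and 2 of the 10 gave as many: the highest other, 1850, put nhm3-1+GA3 replicate 3 with nhm3-1 replicates 1 and 3, which points to a structure of the samples that the labels do not give. For genes that moved back, 3 of 100 splits of the 9 libraries gave 375 or more, a share under 0.05. These 100 were the real split and others drawn at random from all possible ones, so the share is an estimate. It argues against a random grouping at that level without excluding one. The 2 drawn splits that gave as many, up to 1070 genes, again put nhm3-1+GA3 replicate 3 with nhm3-1 replicates 1 and 3. This points to the same structure of the samples, and the share does not exclude that structure.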
